A study of Mus musculus with 8 samples.

How the data were processed

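The series holds 8 RNA-seq libraries from mouse fetal mammary organoid cells of the CD1 strain. Per the labels' protocols, fetal mammary stem cells were sorted from embryos at day 17.5, infected with a lentivirus that carries human Sox10 joined through a 2A peptide to a nuclear Venus protein under a doxycycline-responsive promoter, and grown as organoids. Doxycycline (dox) was given 72 hours after plating, and dissociated cells were sorted into Venus-positive and Venus-negative fractions. Cells of organoids without virus, and of organoids with virus but no dox, were recovered in parallel. Each of the 4 groups has 2 libraries, which the labels call biological replicates. The titles number them 22 and 30, and the header of the deposited table places the 30 libraries in its first experiment and the 22 libraries in its second. They are called experiment 22 and experiment 30 here.

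Libraries were made with the TruSeq RNA kit and sequenced as paired reads of 100 bases, per the labels' protocols. Reads were handled with STAR and Cufflinks on the GRCm38 (mm10) genome, per the submitters' processing notes; versions, the gene annotation and the strand setting are not given in the sources used here. The authors deposited FPKM (fragments per kilobase of transcript per 1e+06 fragments) with 2 decimals, so raw counts were not analysed here. The table's 2 side-by-side blocks were joined by gene ID. Of 38583 features, 38483 are genes and 100 are not, including 92 ERCC spike-in features that are listed at 0 in all libraries. The features that are not genes took at most 0.113% of a library's FPKM and stayed out of the tests. Symbols for 36639 gene IDs came from a reference table of mouse gene names. The other 1844 kept the symbol in the file or, without one, their ID. Coordinates are those of GENCODE release vM21 on GRCm38.

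Depth was estimated from the FPKM values. For genes with 1 transcript in the table, FPKM multiplied by length in kilobases takes regularly spaced values at the low end, and the spacing gives the number of fragments behind the scale. A spacing was found in 7 libraries, where 79.1% to 85.7% of the low values lay within 0.2 of a whole fragment. It gave 12.2 and 8.17 M fragments (M is 1e+06) for uninfected cells of experiments 22 and 30, 8.62 and 6.98 M for infected cells without dox, 7.95 M for Venus-negative cells of experiment 30, and 4.39 and 4.61 M for Venus-positive cells. Low values of the Venus-negative library of experiment 22 showed no clear spacing. These are estimates from rounded values, and no counting interval is given from them.

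The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 as 4 group means over all 8 libraries, with moderation along the mean-variance trend (4 residual degrees of freedom). Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 13817 in all. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes, and errors are standard errors (SE) of the fit. All groups share 1 estimate of each gene's spread, which includes the spread between the Venus-positive libraries. The SD over genes of the log2 difference between replicates was 0.998 in Venus-positive cells. It was 0.722 in uninfected cells, 0.458 in infected cells without dox and 0.600 in Venus-negative cells. The shared estimate can therefore make p values too small for Venus-positive cells and too large among the 3 other groups. The contrasts were Venus-positive cells against each other group and against the mean of the 3 other groups, and the 3 comparisons among those groups.

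There were 30 gene lists with 693 entries, of which 570 were tested; 27 genes stood in more than 1 list. They covered Sox10 targets of neural crest and glia, cell states and pathways, markers of other cell types, and RNA quality (mitochondrially encoded genes and cytoplasmic ribosomal proteins). Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a contrast. An estimated correlation and limma's fry served as alternatives. Members past the threshold were counted over all genes tested and adjusted over the list alone. The named genes were Sox10; among changed genes with no overlap between the libraries compared and a higher mean of at least 5 FPKM, the 10 largest rises and 10 largest falls against the 3 other groups and the 5 and 5 against each single group; and up to 4 members of each list by smallest p against the 3 other groups. Where fewer than 5 genes passed, the 5 with the smallest p were named. Predicted genes and models without a symbol were counted and not named, apart from Gm12918, which alone made up a count. A gene that met the rule is not reported here.

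Because the table's header assigns the replicate numbers to experiments, the numbers were taken to pair the samples. The differences between experiments 22 and 30 correlated across genes between groups by -0.02 to 0.24, above 0.1 in 2 of 6 pairs of groups. A fit with the experiment as an additive term was run as an alternative. The other alternatives were a pseudocount of 0.1, no filter (any value above 0), a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, robust moderation, a fit of only the groups compared, and the omission of each library in turn with the tested genes kept. Setting values under 1 to 1 was added after seeing that the libraries differ in depth. Count models were not run, since the values are FPKM.

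The fit was tested on simulated data with 200 changed genes per comparison, 100 of them at 2-fold and 100 at 4-fold. Each simulated gene had the same spread in all groups, unlike the real replicates. For Venus-positive cells against the mean of the 3 other groups it recovered 33% of the 2-fold and 95% of the 4-fold changes among 13403 genes. For infected cells without dox against uninfected cells it recovered 10% and 77% among 13410 genes. The 3 comparisons of Venus-positive cells with single groups share the Venus-positive libraries, so the overlap of their calls was set beside 20 simulations of unchanged groups.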

Results

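Gene expression was measured in 8 libraries of mouse fetal mammary organoid cells, to ask what changes in cells made to express ectopic Sox10, a transcription factor of neural crest, glia and mammary cells. Venus-positive cells carried the active transgene. The other groups were Venus-negative cells of the same dox-treated cultures, infected cells without dox and uninfected cells, each with 2 libraries, 1 from each of 2 experiments numbered 22 and 30. Between 11990 and 12938 genes reached 1 FPKM in a library. Venus-positive libraries were the shallowest of the 7 with a depth estimate, at 4.39 and 4.61 M fragments against 6.98 to 12.2 M, and so are the least precise for low genes. Over all tested genes, Venus-positive 30 correlated more with no-dox 30 (r = 0.896) than with Venus-positive 22 (r = 0.886). Uninfected 22 stood apart from the 5 other libraries that were not Venus-positive, with a median r of 0.918 and scores of 54.0 and 42.3 on principal components 2 and 3. Venus-negative 30 did so as well, with a highest r of 0.951, a score of -51.3 on component 4 and 14.8% of its FPKM in mitochondrially encoded genes. Median-of-ratios scaling would have moved no library by more than 0.0420 on the log2 scale.

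Sox10 (ENSMUSG00000033006; GRCm38 chromosome 15, 79154908 to 79165240, minus strand) was highest in the Venus-positive libraries, at 549 and 459 FPKM in experiments 22 and 30. It stood at 30.1 and 39.2 FPKM in Venus-negative cells, 39.6 and 57.7 FPKM in infected cells without dox, and 5.91 and 12.8 FPKM in uninfected cells. On the log2(FPKM + 1) scale it was higher by 3.83 ± 0.34 (SE) than in Venus-negative cells (limma adjusted p = 0.00175), by 3.37 ± 0.34 than without dox (limma adjusted p = 0.00311) and by 5.69 ± 0.34 than in uninfected cells (limma adjusted p = 0.000499). When only the groups compared were fitted, the last 2 adjusted p values became 0.0506 and 0.0504. The transgene is human, and reads from it may have been assigned to the mouse gene, so this value can mix the transgene and the endogenous gene. A feature of the table named for spliced GFP, which is related in sequence to Venus, was at 601 and 420 FPKM in Venus-positive cells and at 1.89 to 7.69 FPKM in the 6 other libraries.

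**Figure D1:**
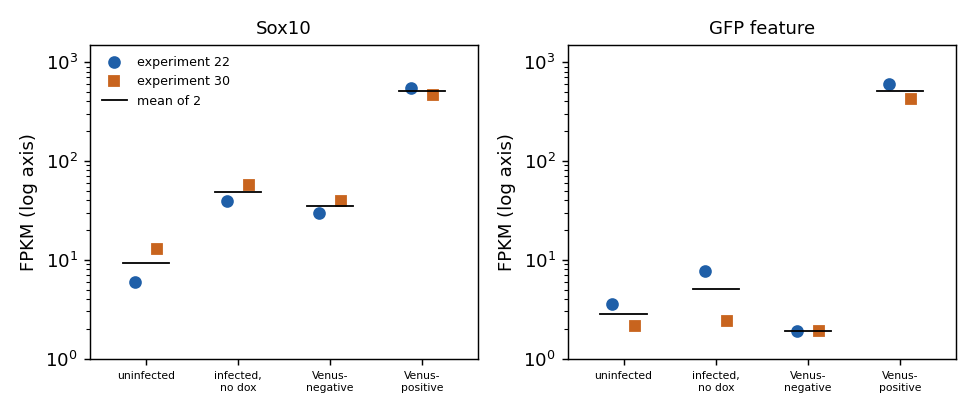
FPKM of Sox10 and of the GFP feature per library, on log axes, for the 4 groups; circles are experiment 22, squares experiment 30 and lines the mean of 2 libraries. Both measures were highest in the Venus-positive libraries, and Sox10 was lowest in uninfected cells, at 5.91 and 12.8 FPKM.

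Against the mean of the 3 other groups, 2497 genes changed in Venus-positive cells, 1280 higher and 1217 lower (limma, adjusted p under 0.05, 13817 genes tested). Of these, 850 were higher and 866 lower by more than 1 on the log2 scale. The largest rise was in Serpina3n, a secreted serine protease inhibitor, at 546 and 251 FPKM against at most 8.57 FPKM in any other library (log2 change 7.20 ± 0.79 SE, limma adjusted p = 0.00147). Tnfrsf19 (chromosome 14, 60963875 to 61046490, minus strand), a receptor of the tumour necrosis factor family, was at 216 and 108 FPKM against at most 1.43 FPKM (6.86 ± 0.42, adjusted p = 0.000244). Tmem35a, Kif19a, A2m, Enpp2, Ptgds, Nxf7 and Pmel rose by 5.59 to 6.29 on the same scale. Enpp2 encodes autotaxin, Ptgds a prostaglandin D synthase and Pmel a melanosome protein. Kif19a and A2m were listed at 0 in both uninfected libraries.

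The largest fall was in Vnn1, a pantetheinase, from 29.1 to 119 FPKM in the other libraries to 3.70 and 1.17 FPKM (log2 change -4.07 ± 0.39 SE, limma adjusted p = 0.000965). Kazald1 stood at 32.5 to 41.1 FPKM elsewhere and at 1.91 and 2.09 FPKM in Venus-positive cells (-3.66 ± 0.18, adjusted p = 0.000188). Slpi, a secreted protease inhibitor, fell from 295 to 638 FPKM to 34.9 and 40.5 FPKM. Postn, the matrix protein periostin, fell from 122 to 187 FPKM to 5.18 and 23.8 FPKM, and Hp, haptoglobin, from 49.1 to 187 FPKM to 6.09 and 5.45 FPKM. The chemokine Cxcl15, the calcium-binding S100a14 and the cornified envelope gene Sprr1a fell (log2 changes -3.68, -4.06 and -3.81). Mxra8 was listed at 0 in both Venus-positive libraries and at 6.36 to 33.4 FPKM elsewhere. Rpl35a-ps2 also passed (adjusted p = 0.0444), but it is a processed pseudogene whose reads can be shared with its parent gene, and its call was lost without any 1 library except Venus-positive 30 (adjusted p 0.0678 to 0.113). The call of Sprr1a was lost without Venus-positive 22 (adjusted p = 0.0608).

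Omission of single libraries moved the count of 2497 by more than 1.5 times in 4 cases: to 1343 without Venus-positive 22, 3933 without Venus-positive 30, 1216 without the no-dox library of experiment 22 and 1300 without that of experiment 30. With no filter on low values, 1468 of 23248 genes passed. The share of higher genes among those called, 51.3%, ranged from 47.7% to 57.0% over all settings and omissions, so neither direction prevailed.

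**Figure D2:**
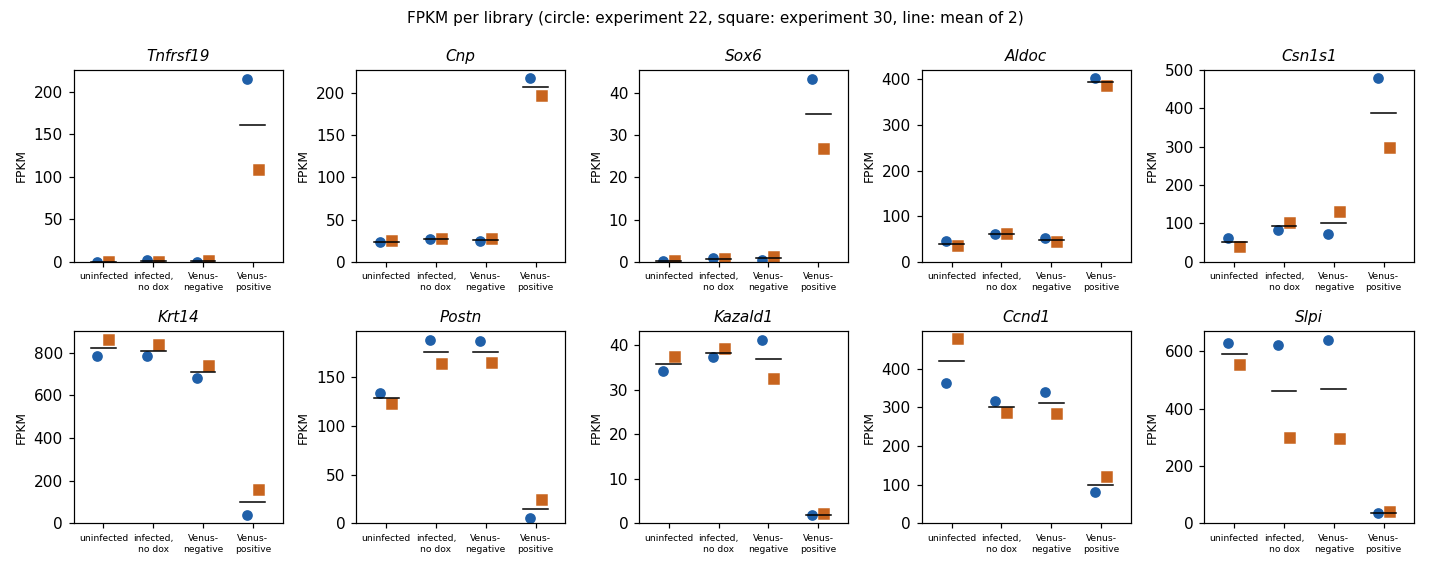
FPKM per library of 10 named genes in the 4 groups; circles are experiment 22, squares experiment 30 and lines the mean of 2 libraries. Tnfrsf19, Cnp, Sox6, Aldoc and Csn1s1 were higher in both Venus-positive libraries than in all 6 others, and Krt14, Postn, Kazald1, Ccnd1 and Slpi were lower.

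Of the 30 gene lists, 13 changed against the 3 other groups, 3 higher and 10 lower, by camera at the preset correlation. None held with an estimated correlation, where the smallest adjusted p was 0.236, so list directions describe these libraries and the preset test. The estimate lay under the preset 0.01 for Sox10 targets (0.00675), milk production (-0.00585) and keratinocytes (-0.0164). A higher correlation of members therefore does not explain the loss of those lists, whose cause was not tested. In the other changed lists the estimate ran from 0.0325 (hypoxia and glycolysis) to 0.676 (basal and myoepithelial cells). Known Sox10 targets of neural crest and glia were higher as a list, with 12 of 23 tested members higher and 1 lower, and 14 and 2 adjusted over the list alone (camera adjusted p = 1.31e-05; adjusted p = 0.236 with an estimated correlation). Cnp, an enzyme of myelin-forming cells (chromosome 11, 100574904 to 100591729), rose from 23.1 to 27.0 FPKM to 218 and 196 FPKM (log2 change 2.98 ± 0.13 SE, limma adjusted p = 0.000188). Sox6 and S100b rose by 4.50 and 4.67. Of 13 Schwann cell markers 8 were tested, and of 10 melanocyte markers 7. In the Schwann cell list, 3 of the 8 tested members were higher and 0 lower, 3 and 1 adjusted over the list alone (camera adjusted p = 0.252; 0.00915 by fry). The gap junction gene Gjc3 rose by 2.52, and Mbp, a myelin protein, by 0.89 ± 0.23 (adjusted p = 0.0316), a call that was lost without any 1 of 6 libraries (adjusted p 0.0524 to 0.0973). Ncmap was listed at 0 in both Venus-positive libraries and did not pass. Markers of melanocytes had 3 of 7 members higher and 0 lower by both counts (camera adjusted p = 0.0559), and passed without no-dox 22 (adjusted p = 0.0244), Venus-negative 22 (0.0452) or Venus-positive 22 (0.0494). They passed against no-dox (0.0487, and 0.0561 with the replicate block) and uninfected cells (0.0387) but not against Venus-negative cells (0.0913). With an estimated correlation the adjusted p was 0.392 in both of the former, and 0.464 against the mean, where fry gave 0.0184. Pmel rose by 5.59, and Mitf, the melanocyte master regulator, from 1.24 to 2.70 FPKM to 15.0 and 13.6 FPKM, while Tyrp1 was listed at 0 in both Venus-positive libraries. Kit, a receptor also of luminal progenitors, rose by 1.41, a call lost without Venus-positive 22 (adjusted p = 0.0932).

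Genes of hypoxia and glycolysis were higher as a list, with 11 of 30 higher and 2 lower, and 12 and 2 adjusted over the list alone (camera adjusted p = 0.000419; adjusted p = 0.263 with an estimated correlation). The glycolytic enzyme genes Aldoc, Aldoa, Pfkl and Eno1 led it. Aldoc rose from 33.7 to 60.0 FPKM to 403 and 386 FPKM (log2 change 3.01 ± 0.15 SE, limma adjusted p = 0.000188), Aldoa by 1.75, Pfkl by 1.77 and Eno1 by 1.36. Milk production genes were also higher, with 4 of 11 higher and 0 lower, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.263 with an estimated correlation). The casein gene Csn1s1 rose from 37.2 to 130 FPKM to 478 and 296 FPKM (2.31 ± 0.30, adjusted p = 0.00278). Csn1s2a and Csn2, low elsewhere, reached 19.5 and 7.37 FPKM and 6.50 and 2.80 FPKM. Plin2, a lipid droplet protein gene, rose by 0.65, a call lost without the no-dox library of experiment 30 (adjusted p = 0.0630) or Venus-positive 22 (adjusted p = 0.0615).

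Hormone-sensing luminal genes were lower, with 8 of 14 lower and 1 higher, and 11 and 1 adjusted over the list alone (camera adjusted p = 0.000657; adjusted p = 0.466 with an estimated correlation). Ptn fell from 213 to 297 FPKM to 63.6 and 87.6 FPKM, and Ly6a, Wnt4 and the oestrogen receptor gene Esr1 fell (log2 changes -3.31, -1.72 and -2.02). Basal and myoepithelial genes had 8 of 23 lower and 3 higher, 11 and 4 adjusted over the list alone (camera adjusted p = 0.0316; adjusted p = 0.646 with an estimated correlation and 0.246 by fry). The basal keratin Krt14 (chromosome 11, 100203162 to 100207548) fell from 682 to 859 FPKM to 40.8 and 156 FPKM (log2 change -3.26 ± 0.41 SE, limma adjusted p = 0.00235), Krt17 fell from 123 to 207 FPKM to 30.9 and 60.5 FPKM, and the laminin gene Lamb3 fell by 1.99 on the log2 scale. The fall of the list depended on the group compared: its mean difference was -0.95 against Venus-negative cells (camera adjusted p = 0.00207) and -0.90 against no-dox cells (camera adjusted p = 0.00925), but -0.23 against uninfected cells, where it did not pass (camera adjusted p = 0.323). The first 2 calls were lost with an estimated correlation (adjusted p = 0.581 and 0.572) and by fry (adjusted p = 0.230 and 0.242). In Venus-negative and no-dox cells the same list lay 0.72 and 0.66 above uninfected cells (camera adjusted p = 1.64e-05 and 0.000932; adjusted p = 0.619 and 0.757 with an estimated correlation), in comparisons where a list of RNA quality passed too: ribosomal proteins lower in Venus-negative cells (camera adjusted p = 2.17e-05; adjusted p = 0.487 with an estimated correlation) and mitochondrially encoded genes lower in no-dox cells (camera adjusted p = 0.000618; adjusted p = 0.729 with an estimated correlation). In contrast, the oxytocin receptor gene Oxtr, a myoepithelial marker, rose from 9.50 to 64.9 FPKM to 255 and 208 FPKM. Luminal progenitor genes did not pass as a list (camera adjusted p = 0.320), except against no-dox cells alone (0.0360; 0.392 with an estimated correlation), while fry called it (0.0401), with 3 of 20 higher and 4 lower, and 4 and 4 adjusted over the list alone: Plet1, Cxcl1 and Aldh1a3 fell (log2 changes -2.60, -2.69 and -1.66), and Hey1 rose by 1.34. Epithelial adhesion and identity genes were lower, with 10 of 40 lower and 1 higher, 13 and 2 adjusted over the list alone (camera adjusted p = 0.0316; adjusted p = 0.552 with an estimated correlation). Against Venus-negative cells of the same cultures this list did not pass (mean -0.24, camera adjusted p = 0.113). Krt19, Krt7, Cldn4 and Pkp1 fell (log2 changes -1.36, -2.42, -2.01 and -1.07).

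Genes of the mesenchymal state were lower, not higher, as a list, with 6 of 22 lower and 3 higher, 9 and 4 adjusted over the list alone (camera adjusted p = 0.0329; adjusted p = 0.497 with an estimated correlation). The matrix enzyme genes Mmp3 and Lox were listed at 0 or 0.05 FPKM in Venus-positive cells and at 3.31 to 15.8 FPKM elsewhere, Foxc1 fell by 1.26, and Tcf4 rose by 1.31. Wnt target genes had 7 of 13 lower and 1 higher, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.525 with an estimated correlation). Wif1, Ccnd1 (cyclin D1) and Lgr6 fell (log2 changes -2.69, -1.78 and -3.32), and Rnf43 rose by 1.26. Several of these list calls rested on single libraries. Without Venus-positive 22, the adjusted p was 0.224 for the mesenchymal state, 0.215 for basal and myoepithelial cells and 0.0552 for Wnt target genes. Without uninfected 30 it was 0.0523 for the mesenchymal state and the Wnt target genes and 0.0951 for basal and myoepithelial cells. Wnt target genes also missed the threshold without uninfected 22 (0.0560), basal and myoepithelial cells without Venus-negative 30 (0.0784), and epithelial adhesion and identity without Venus-positive 30 (0.171).

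Cell cycle genes were lower, with 13 of 43 lower and 0 higher, and 21 and 0 adjusted over the list alone (camera adjusted p = 5.02e-07; adjusted p = 0.497 with an estimated correlation and 0.0532 by fry). The mitotic kinesin gene Kif23 fell from 12.4 to 21.1 FPKM to 2.87 and 3.04 FPKM (log2 change -2.16 ± 0.26 SE, limma adjusted p = 0.00216). Cdt1, Kif11 and Cdc20 fell (log2 changes -1.24, -1.86 and -1.02), with calls that were lost without Venus-positive 22 for Cdt1 (adjusted p = 0.0507) and Kif11 (0.104) and without Venus-positive 30 for Cdc20 (0.0723); Cdt1 (0.0519) and Cdc20 (0.0566) were also lost without the no-dox library of experiment 30. Genes of the p53 response were lower in 13 of 22 and higher in 0, and 14 and 0 adjusted over the list alone (camera adjusted p = 1.32e-06; adjusted p = 0.386 with an estimated correlation). Plk2 fell from 246 to 303 FPKM to 65.4 and 113 FPKM, and Ccng1, Sesn2 and Phlda3 fell (log2 changes -1.05, -1.54 and -0.72). Immediate early and heat shock genes were lower in 10 of 25 and higher in 0 by both counts (camera adjusted p = 0.000657; adjusted p = 0.466 with an estimated correlation and 0.0543 by fry). Hspb1, Fosb, Klf2 and Klf4 fell (log2 changes -1.28, -3.26, -2.48 and -1.57), and without Venus-positive 22 the adjusted p was 0.0620 for Fosb, 0.0520 for Klf2 and 0.0510 for Klf4. Cytoplasmic ribosomal protein genes, fixed as a sign of RNA quality, were lower in 17 of 65 and higher in 0, and 23 and 0 adjusted over the list alone (camera adjusted p = 3.34e-08; adjusted p = 0.263 with an estimated correlation). This was the smallest camera adjusted p of the 30 lists, and the list was also lower in all 3 single comparisons. Whether RNA quality contributes to the other lower lists was not tested. Rps16 and Rpsa fell (log2 changes -1.22 and -0.93); many of these genes have pseudogene copies, so their values are uncertain. Rpl13 and Rpl4 fell (log2 changes -0.87 and -0.65), but without Venus-positive 22 their adjusted p was 0.0866 and 0.127, and without either no-dox library that of Rpl4 was 0.0642. Mitochondrially encoded genes had 0 of 13 past the threshold by limma in either direction by both counts (camera adjusted p = 0.956), and mt-Atp8, mt-Nd1, mt-Atp6 and mt-Co2 had unadjusted p values from 0.415 to 0.505.

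**Figure D3:**
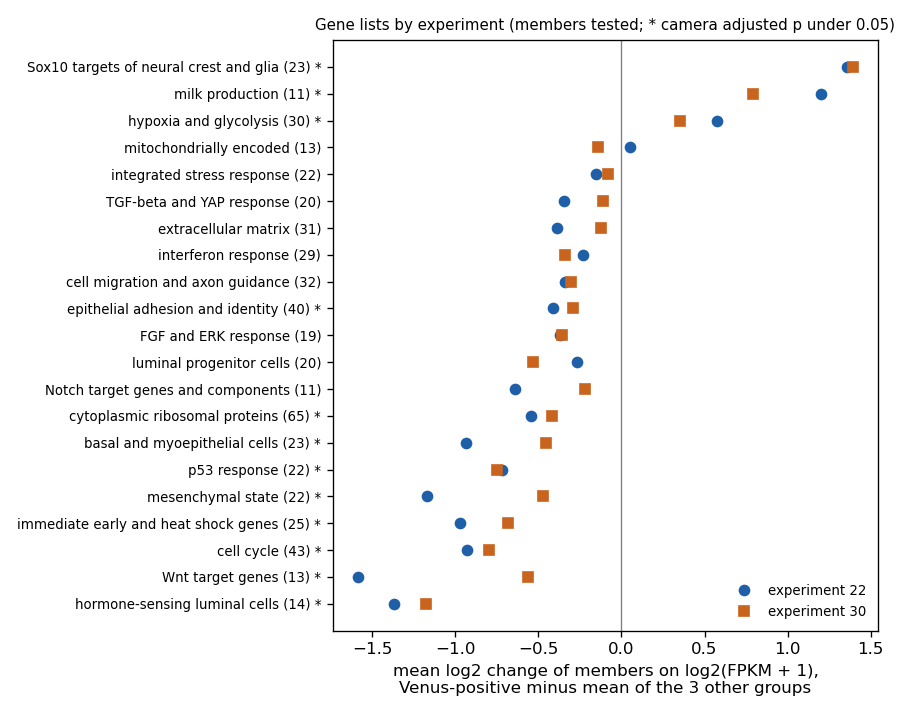
Mean log2 change of the tested members of each pathway and RNA quality list, Venus-positive cells minus the mean of the 3 other groups, in experiment 22 (circles) and experiment 30 (squares); the number of members is in parentheses and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Sox10 targets lay at 1.36 and 1.40 in experiments 22 and 30, and Wnt target genes at -1.59 and -0.56.

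Markers of other cell types were largely below the filter: 2 of 18 leukocyte, 1 of 12 erythroid, 2 of 10 adipocyte, 3 of 12 skeletal muscle, 5 of 14 endothelial and 7 of 18 fibroblast markers were tested. By camera none of these lists passed, with adjusted p of 0.188 for leukocytes, 0.102 for erythroid cells, 0.969 for adipocytes and for skeletal muscle, 0.320 for endothelial cells and 0.347 for fibroblasts. Fry called the leukocyte (adjusted p = 0.0389), erythroid (adjusted p = 0.00627) and endothelial (adjusted p = 0.0402) lists. Single members passed: Cd74 was listed at 0 in both Venus-positive libraries, Flt1 fell by 1.64, Postn fell as above, Alas2, an enzyme gene of haem synthesis, rose by 2.12, and Neb, a muscle gene, by 2.30. Adjusted over the list alone, 1 member passed in each list but adipocytes, where Lipe was higher and Pparg lower. Over all genes Lipe did not pass (adjusted p = 0.0698) until the replicate block was added (adjusted p = 0.0357) or Venus-negative 22 was left out (adjusted p = 0.0432), nor did Pparg (adjusted p = 0.0611). Without Venus-positive 30, Col1a1 (adjusted p = 0.0258) and Egfl7 (adjusted p = 0.0348) also passed. The calls of Cd74 (adjusted p = 0.0534) and Flt1 (adjusted p = 0.0512) were lost without the no-dox library of experiment 22, that of Cd74 also without Venus-positive 22 (adjusted p = 0.0724), and that of Neb without any 1 of 7 libraries (adjusted p 0.0535 to 0.120). Markers of keratinocytes had 2 of 7 lower and 1 higher, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0499; adjusted p = 0.386 with an estimated correlation). This list did not pass against Venus-negative cells alone (camera adjusted p = 0.0913). The list call was lost without uninfected 30 (0.0523), no-dox 30 (0.0565), Venus-negative 22 (0.0504), Venus-negative 30 (0.0697), Venus-positive 22 (0.120) or Venus-positive 30 (0.0624). Krt6a fell by 3.36, and the call of the rising member Sbsn was lost without any 1 library except Venus-positive 30 (adjusted p 0.0503 to 0.123).

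Against Venus-negative cells of the same cultures, 1127 genes changed, 653 higher and 474 lower (limma). The cultures received virus and dox, but whether the Venus-negative cells carried the virus was not tested. The 5 largest rises were Serpina3n, Tnfrsf19, Enpp2, Tmem35a and Kif19a, by 6.24 to 6.86 on the log2 scale. The largest falls were Sprr1a (-4.13 ± 0.83 SE), S100a14 (-3.89 ± 0.97), Postn (-3.83 ± 0.53) and Vnn1 (-3.79 ± 0.48), with Prss23os, an antisense gene, listed at 0 in both Venus-positive libraries; antisense reads cannot be told apart without a stated strand. Most of these falls rested on single libraries: S100a14 missed the threshold without any 1 of the 6 libraries that were not Venus-positive (adjusted p 0.0811 to 0.209), Prss23os without any 1 library that was infected (0.0611 to 0.203), Sprr1a without either no-dox or Venus-negative library or Venus-positive 22 (0.0507 to 0.142), and Postn without Venus-negative 22 (0.0575) or 30 (0.0551). There were 11 lists past the threshold, 3 higher and 8 lower, and 0 with an estimated correlation (smallest adjusted p = 0.247). With the replicate block, milk production (adjusted p = 0.0485 to 0.0551) and Wnt target genes (adjusted p = 0.0493 to 0.0551) no longer passed. With only these 2 groups fitted 134 genes passed, with the 5 rises and Prss23os but not the 4 other falls, and with no filter 456. Single omissions gave 265 without Venus-negative 22, 209 without Venus-negative 30, 563 without Venus-positive 22, 2901 without Venus-positive 30, and 540 and 546 without the no-dox libraries of experiments 22 and 30. The share of higher genes, 57.9%, was 80.6% with only these groups, 70.4% with no filter, 76.6% without Venus-negative 22 and 48.6% without Venus-positive 30, so it is not a stable feature.

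Against infected cells without dox, 1098 genes changed, 587 higher and 511 lower (limma). Tnfrsf19, Serpina3n, Enpp2, A2m and Kif19a rose most, by 5.92 to 6.53 on the log2 scale. S100a14 (-4.28 ± 0.97 SE), Sprr1a (-4.22 ± 0.83), Hp (-3.99 ± 0.63) and Postn (-3.83 ± 0.53) fell most, along with Prss23os. S100a14 missed the threshold without any 1 of the 6 libraries that were not Venus-positive (adjusted p 0.0663 to 0.189), and Prss23os without any 1 library that was infected (0.0594 to 0.221). Without no-dox 22 so did Sprr1a (0.166), Hp (0.0864) and Postn (0.0713), without no-dox 30 Sprr1a (0.125), Postn (0.0591) and Serpina3n (0.0731), and without Venus-positive 22 Sprr1a (0.0804), Hp (0.0519) and Serpina3n (0.0552). There were 15 lists past the threshold, 4 higher and 11 lower, 9 without Venus-positive 22 and 0 with an estimated correlation (smallest adjusted p = 0.247). With the replicate block, melanocytes no longer passed (adjusted p = 0.0487 to 0.0561). With only these 2 groups fitted limma called 0 genes, and with no filter 516. Single omissions gave 71 and 86 without the no-dox libraries of experiments 22 and 30, 726 without Venus-negative 22, 524 without Venus-positive 22 and 2850 without Venus-positive 30. The share of higher genes, 53.5%, was 62.2% with no filter, 81.7% and 66.3% without no-dox 22 and 30, and 46.7% without Venus-positive 30.

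Against uninfected cells, 1644 genes changed, 871 higher and 773 lower (limma). Serpina3n, Tnfrsf19, Tmem35a and Nxf7 rose most, by 6.50 to 8.32 on the log2 scale, and Kif19a stood at 100 and 71.9 FPKM against 0 in both uninfected libraries. Vnn1 (-4.80 ± 0.48 SE), Cxcl15 (-4.63 ± 0.54) and Aldh3a1 (-4.18 ± 0.51), an aldehyde dehydrogenase gene, fell most, together with Mxra8 and the pseudogene Rps26-ps1, which were listed at 0 in both Venus-positive libraries. Rps26-ps1 stood at 133 and 4.36 FPKM in the 2 uninfected libraries, and missed the threshold without any 1 library except uninfected 30 (adjusted p 0.0702 to 0.124). There were 13 lists past the threshold, 4 higher and 9 lower, and 0 with an estimated correlation (smallest adjusted p = 0.182). With only these 2 groups fitted limma called 0 genes, and with no filter 747. Single omissions gave 340 and 876 without uninfected 22 and 30, 876 and 879 without the no-dox libraries of experiments 22 and 30, and 3317 without Venus-positive 30. The share of higher genes was 62.2% with no filter, 68.5% and 60.3% without uninfected 22 and 30, and 47.8% without Venus-positive 30.

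In all 3 single comparisons, 498 genes were higher and 343 lower in Venus-positive cells. Simulated unchanged groups gave 0 in both directions, which was nearly fixed in advance, since no simulated gene differed. Independent lists of these sizes would share 1.75 and 0.981 genes, but the comparisons share the Venus-positive libraries and are not independent. Neither value shows how much of the overlap comes from those libraries.

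Among the 3 groups other than Venus-positive cells, limma called 0 genes in each comparison. At an unadjusted p under 0.05 there were 40 genes between Venus-negative and no-dox cells, 396 between Venus-negative and uninfected cells, and 410 between no-dox and uninfected cells. The 5 genes with the smallest p between no-dox and uninfected cells, none past the threshold, were Apod, Snorc, Atp6v1b1, Sox10 and Elf5. Apod, a lipid-binding apolipoprotein, was at 74.4 and 57.9 FPKM without dox and 8.46 and 10.8 FPKM in uninfected cells (log2 difference 2.66 ± 0.29 SE, limma adjusted p = 0.217), and passed without Venus-positive 30 (adjusted p = 0.0462). Elf5, a transcription factor of the luminal progenitor lineage, was at 40.1 and 54.3 FPKM against 18.7 and 14.2 FPKM (adjusted p = 0.737). Apod stood at 51.9 and 51.3 FPKM in Venus-negative cells and was highest in Venus-positive cells, at 445 and 246 FPKM. Between Venus-negative and uninfected cells the 5 genes were Apod (limma adjusted p = 0.586), Sox10, Muc15, Snorc and Atp6v1b1, again not past the threshold. Between Venus-negative and no-dox cells they were Snora30, Depp1, Hist1h2bm, Gadd45b and Rps16, all with adjusted p = 1.

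The lists past camera's preset test numbered 7, 9 and 7 in the comparisons Venus-negative against no dox, Venus-negative against uninfected, and no dox against uninfected. Of these, 0 passed with an estimated correlation, and fry called 0 in each. In Venus-negative against no-dox cells, mitochondrially encoded genes were higher by 0.44, and immediate early and heat shock, luminal progenitor, ribosomal protein, epithelial, Notch, and TGF-beta and YAP genes were lower (camera adjusted p 3.03e-08 to 0.0219; adjusted p = 0.505 with an estimated correlation). The mitochondrial difference came from experiment 30 and was -0.11 in experiment 22, and that of immediate early genes was -0.69 in experiment 30 and -0.03 in experiment 22. Against uninfected cells, the basal, luminal progenitor, milk and extracellular matrix lists were higher in both Venus-negative and no-dox cells, the matrix list by 0.43 in each, and the p53 response was lower. The p53 difference came from experiment 30, at -0.61 in Venus-negative and -0.53 in no-dox cells. In experiment 22 it was 0.03 and -0.04. Venus-negative cells were also lower in the immediate early, integrated stress response, adipocyte and ribosomal protein lists, and no-dox cells higher in Sox10 targets and lower in mitochondrially encoded genes (camera adjusted p 1.37e-08 to 0.0498; adjusted p 0.419 to 0.757 with an estimated correlation). In Venus-negative cells the immediate early and ribosomal protein lists were lower in experiment 30 (-0.64 and -0.29) but not in experiment 22 (0.07 and 0.09). With the replicate block, the Sox10 targets no longer passed between no-dox and uninfected cells (adjusted p = 0.0413 to 0.0559), nor did the integrated stress response between Venus-negative and uninfected cells (adjusted p = 0.0498 to 0.0664), where the TGF-beta and YAP response (adjusted p = 0.0888 to 0.0493) and fibroblasts (adjusted p = 0.0893 to 0.0448) passed instead. Omitting uninfected 22 changed the last 2 numbers to 5 and 4, and omitting uninfected 30 changed the 9 to 4. Other single omissions called 1 gene each: the pseudogene Rpl17-ps5 without uninfected 30, and the predicted gene Gm12918 without Venus-negative 22.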

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

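All tests of explanations in this part were chosen after the result was seen. Features of the table that are not genes were set beside the uninfected libraries. The GFP feature was at 7.69 FPKM in infected cells without dox of experiment 22, above both uninfected libraries (3.53 and 2.16 FPKM), and at 600.78 and 420.45 FPKM in Venus-positive cells. In the same no-dox library Serpina3n was at 8.57 FPKM and Tmem35a at 2.36 FPKM, against 0.94 and 0.78 FPKM in the no-dox library of experiment 30. Serpina3n did not follow the GFP feature everywhere: in Venus-negative 30 it was at 7.01 FPKM, with the GFP feature at 1.89 FPKM and Tmem35a at 0.81 FPKM. A feature named for a GFP reporter of the mouse L1 element was above the uninfected libraries (0.96 and 0.38 FPKM) in 4 libraries: 1.42 FPKM in no-dox 22, 1.39 FPKM in Venus-negative 22, and 1.09 and 1.34 FPKM in Venus-positive cells.

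Sox10 was 30.1 to 57.7 FPKM in infected cells without dox and in Venus-negative cells, and 5.91 and 12.8 FPKM in uninfected cells. If this excess came from the transgene, GFP would rise with it at the ratio seen in Venus-positive cells (1.09 and 0.916 in experiments 22 and 30). GFP reached at most 20.9% of that level in the 4 libraries, with its level in uninfected cells not subtracted. This argues against the transgene as the whole source. In Venus-negative cells GFP (1.92 and 1.89 FPKM) was below both uninfected libraries (3.53 and 2.16 FPKM), so it showed no excess there. In no-dox 30, at 2.41 FPKM, it lay between the uninfected libraries. Uninfected 22 as a single odd library cannot make the whole difference. Uninfected 30 also lay below the lowest of the 4 libraries, by 1.23 on the log2 scale, and the SD of the 4 was 0.387. The 2 uninfected libraries differed between themselves (5.91 and 12.8 FPKM), so 1 of them cannot show whether their spread accounts for the gap. Neither Sox10 difference from uninfected cells passed the limma threshold. For a lower share of luminal progenitor cells in uninfected organoids, the list median was higher by 0.31 (SD 0.61) in Venus-negative and 0.52 (SD 0.65) in no-dox cells and Sox10 by 1.85 and 2.32, a shortfall of at least 1.54. A change in cell share would move each gene by how specific it is to those cells. The shortfall therefore cannot decide this explanation. The virus itself may also act, and it was not tested, because infection separates the same groups.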

How the results depend on the processing

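Setting values under 1 to 1, and the alternatives for genes named in single comparisons, were chosen after seeing the data; all other settings were planned. No result reversed. The counts of changed genes stayed within 1.5 times under a pseudocount of 0.1, a filter at 5 FPKM, both scalings, robust moderation, the replicate block and values under 1 set to 1. The replicate block gave 1225, 1165, 1654 and 2584 genes against Venus-negative, no-dox and uninfected cells and their mean. Among the named genes it changed only the calls of Bst2 and Lipe, and against the mean of the 3 groups it changed no list call. In the other comparisons it changed 7 list calls: milk production and Wnt target genes against Venus-negative cells, melanocytes against no-dox cells, 3 lists between Venus-negative and uninfected cells and the Sox10 targets between no-dox and uninfected cells. With no filter the 4 counts were 456, 516, 747 and 1468, where more genes were tested, and 8 lists changed against the mean. With only the groups compared they were 134, 0 and 0, where 2 residual degrees of freedom remain, and Sox10 kept its differences of 3.37 and 5.69 with an adjusted p just over the threshold. Camera with an estimated correlation called 0 lists in all 7 comparisons, and fry called 10, 11, 14 and 18 against Venus-negative, no-dox and uninfected cells and their mean and 0 in the 3 comparisons among those groups. Against the mean, fry did not call the cell cycle, immediate early and heat shock, or basal and myoepithelial lists, and it added luminal progenitors, the integrated stress response, FGF and ERK response, endothelial cells, leukocytes, erythroid cells, melanocytes and Schwann cells.

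Without 1 library at a time, where the lone library of a group is assumed to vary like the others, the counts ranged from 209 to 2901 against Venus-negative cells, 71 to 2850 against no-dox cells, 340 to 3317 against uninfected cells and 1216 to 3933 against their mean. They ranged from 0 to 1 in the 3 comparisons among the other groups. The lists changed ranged from 9 to 15 against no-dox cells, from 4 to 13 between Venus-negative and uninfected cells, and from 4 to 10 between no-dox and uninfected cells. In the omissions, calls of the genes named against the mean were lost 63 times and gained 5 times, and calls of those named in a single comparison were lost 47 times and gained 1 time. The cause was not tested, but the loss of 1 library also leaves 3 residual degrees of freedom. The edgeR test planned for counts was not run, since the values are FPKM. Depth limits low genes most in Venus-positive cells.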

Other observations

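Venus-positive cells differed in growth factor, signalling and matrix genes whose lists did not pass camera at the preset correlation. Notch genes had 2 of 11 higher and 5 lower by both counts (camera adjusted p = 0.347): Notch1 fell from 62.5 to 74.4 FPKM to 18.2 and 34.4 FPKM, Nrarp and Notch3 fell (log2 changes -2.82 and -1.11), while Hey1 rose by 1.34. Without Venus-positive 22 the call of Notch3 was lost (adjusted p = 0.0720). TGF-beta and YAP response genes had 4 of 20 higher and 5 lower, 5 and 6 adjusted over the list alone (camera adjusted p = 0.320). Tgfb2 rose from 1.91 to 4.97 FPKM to 33.9 and 22.5 FPKM, as Tgfb3 fell by 1.71, Tgif1 by 0.99 and Id2 rose by 1.53. Matrix genes went both ways, with 6 of 31 higher and 7 lower, 6 and 11 adjusted over the list alone (camera adjusted p = 0.360). Lama4 rose from 16.9 to 25.3 FPKM to 106 and 97.2 FPKM and Col9a3 rose by 1.95, while Col18a1 fell by 2.14.

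FGF and ERK response genes had 3 of 19 higher and 5 lower, 3 and 8 adjusted over the list alone (camera adjusted p = 0.159; 0.00282 by fry): Fgfbp1 and Dusp6 fell (log2 changes -2.59 and -0.99), Fgfr1 fell by 1.01 and Etv5 rose by 0.72. The call of Fgfr1 was lost without Venus-positive 22 (adjusted p = 0.0835) or no-dox 22 (adjusted p = 0.0519), and that of Etv5 without Venus-positive 30 (adjusted p = 0.0636) or no-dox 22 (adjusted p = 0.0597). Guidance and migration genes had 4 of 32 higher and 11 lower, 6 and 14 adjusted over the list alone (camera adjusted p = 0.252): Ntn1, Unc5b and Epha2 fell (log2 changes -1.83, -1.39 and -1.25), and Sema3e rose by 2.00. Integrated stress response genes had 3 of 22 higher and 2 lower, 3 and 6 adjusted over the list alone (camera adjusted p = 0.451; 0.0423 by fry). Phgdh, the first enzyme of serine synthesis, fell from 71.9 to 118 FPKM to 33.7 and 34.9 FPKM, and Vldlr rose by 1.25. Cebpb fell by 1.42 and Aldh1l2 rose by 1.52, but both calls were lost without Venus-positive 22 (adjusted p = 0.0752 and 0.0508), and that of Aldh1l2 also without no-dox 22 (adjusted p = 0.0551). Interferon response genes had 1 of 29 higher and 1 lower over all genes and 0 adjusted over the list alone (limma; camera adjusted p = 0.451). Mx2, a polymorphic pseudogene in mice and so uncertain, rose by 2.53, a call lost without Venus-positive 22 (adjusted p = 0.121), Venus-negative 30 (adjusted p = 0.0502) or no-dox 30 (adjusted p = 0.0564), and Dhx58 was listed at 0 in both Venus-positive libraries, with a call lost without any 1 library of the no-dox, Venus-negative or Venus-positive groups (adjusted p 0.0565 to 0.119). Bst2 differed by -2.13 (adjusted p = 0.0549), and passed with the replicate block (adjusted p = 0.00430) and without Venus-positive 22 (adjusted p = 0.0353). Rtp4 (adjusted p = 0.0580) passed without Venus-positive 30 (adjusted p = 0.0115).

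Of the tests of the 2 patterns below, only the prediction for thinning to equal depth was written before its result was seen, and all were chosen after the patterns were seen. The changes were smaller in experiment 30 in both directions: the median log2 change was -1.55 in experiment 22 and -1.10 in experiment 30 for the 1217 lower genes, and 1.41 and 1.11 for the 1280 higher genes. Carry-over of Venus-negative cells into the experiment 30 sort may shrink both, and would need a median share of 19.1% from 952 falls (quartiles -0.795% and 38.2%) and 28.6% from 1080 rises (quartiles -12.6% and 55.2%). Of 271 abundant falling genes, 7 kept less of their Venus-negative level than the first median and 0 less than 50 percent of it (33 and 3 for the other median), with the lowest at 11.9% (Plet1). Carried-over cells with the average profile of Venus-negative 30 would add the same share of every gene, so no gene could keep less than that share. On that assumption the lowest gene would limit the share to 11.9%. The profile of any carried-over cells is not known, and Venus-negative 30 itself stood apart from other libraries. The criterion set for this test could not tell for either median, so carry-over stays open. A lower transgene level may contribute as well, since GFP in experiment 30 was 0.700 times and Sox10 0.835 times that of experiment 22. With 1 Venus-positive library per experiment, these cannot be told apart.

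Venus-positive libraries listed 12828 and 14335 genes above 0, against 14088 to 17579 in the 5 other libraries with a depth estimate. Venus-negative 22, which has no depth estimate, listed 22072. Of these, 9242 lay under 1 FPKM, against 838 to 4641 in the rest. Thinned to 4.61 M fragments, the 5 other libraries with a depth estimate would list -4.89% (uninfected 22) to 21.8% more single-transcript genes than the higher Venus-positive library. Lower depth therefore may not account for the whole gap to the 4 others, but uninfected 22 fell below, so it cannot be told. Fewer distinct RNA molecules in the library may also lower the count; the ratio of genes at about 1 fragment to those at about 2 or 3 was 1.71 and 0.647 in the Venus-positive libraries, which gives no common direction.

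Mitochondrially encoded genes took 14.8% of the FPKM in Venus-negative 30 and 10.9% in uninfected 22, against 7.23% to 9.08% in the 6 other libraries. Some genes were low in 1 library alone: Rpl17-ps5 was at 0.34 FPKM in uninfected 22 and at 89.4 to 190 FPKM elsewhere, and Gm12918 at 21.7 FPKM in Venus-negative 30 and at 332 to 460 FPKM elsewhere.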
